A study of Arabidopsis thaliana with 6 samples.

How the data were processed

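Total RNA of cat2-2 rosettes was hybridised to Affymetrix ATH1 arrays, 3 of untreated and 3 of treated plants. Per the labels' protocols, each replicate pooled many rosettes, the RNA was spiked with bacterial control transcripts and labelled by 3' in vitro transcription, and plants grew on sucrose-containing medium. The deposited values are log2 expression levels per probe set, made by the authors with RMA per the submitters' processing notes, which name no version. Whether arrays of other samples were normalized together with these 6 is not given in the sources used here. The second genotype named in the series' design was not analysed here. Samples were grouped by their titles, and the replicates are labelled biological; what else they share, such as plates, is not given in the sources used here. The table held 0 columns of other samples.

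Of 22810 probe sets, 64 Affymetrix control sets were kept apart and 22746 were tested with no filter on low values. Gene names came from the array's platform table, updated through the RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the tested probe sets, 13513 named 1 gene, 503 named several and 8730 were not listed and stayed unnamed, which leaves 4221 of the changed ones without a name. A gene was represented by its probe set with the highest mean over all arrays, which gave 13356 genes, of which 1556 had a symbol other than a locus tag. The 3 catalase genes had been set as a result, but no probe set could be tied to them through these tables, so they are not analysed here.

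Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings, treated minus untreated, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A fold change is 2 to the power of the difference of mean RMA log2 values. The median standard error of a log2 fold change was 0.09, and with 3 arrays per group the number of arrays limits the precision. The 3' minus 5' difference of control transcripts was compared with an exact two-sided permutation test. Python 3.11.15 with pandas 2.3.3 joined the annotation and matplotlib 3.10.9 drew the plots.

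Before the data were examined, 26 gene lists with 530 entries were fixed, and a member counted only where its locus carried one of the accepted symbols in the tables. This left 69 measured entries in 22 lists; 11 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and the other 11 are described by their members. Lists of photoprotection and of flower, vascular and epidermis markers had no member measured here under this rule. A further 51 lists were set after the gene table was seen but before any value was: 43 families of genes that share a symbol prefix and 8 lists of organelle genes, ribosomal proteins, amino acid breakdown and further heat shock genes. They were adjusted among themselves. A list of 36 carbon starvation marker loci was set after the increase of amino acid breakdown genes was seen and before the values of its members were.

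The rule for named genes, also fixed before the data were examined, takes the 10 largest increases and the 10 largest decreases among genes with a symbol that pass the threshold, have groups that do not overlap and lie in the upper 60% of mean levels. From each list it takes the 2 members with the largest changes past the threshold and the largest in the other direction, or the largest member as a value where none passed. A symbol was read as one other than a locus tag. Genes named beyond the rule are other members of the lists and the strongest genes with only a locus tag, which were chosen after their values were seen.

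Where moderation was changed, lists were tested with cameraPR on z scores, so for lists the effects of moderation and of the changed test cannot be told apart. The steps were tested on simulated data of the treated against untreated comparison, with 200 of 22746 probe sets changed. Of those changed by a log2 size of 0.5, 60 of 67 (89.6%) were recovered, of those changed by 1, 67 of 67, and of those changed by 2, 66 of 66, with 20 false calls in all. The simulated noise was independent between probe sets, and far fewer changed than the 9479 called in the data. These rates check the steps and do not describe the real comparison. Alternatives were the replicate number as a block, leaving out the dimmest 40% of probe sets, shifting arrays to equal medians, repeated quantile normalization, trend and robust moderation, no moderation, array weights, leaving out probe sets with shared probes, an adjusted p of 0.01, limma's treat at a log2 size of 0.5, other forms of the list test, and leaving out each array in turn. Anchoring the arrays on the poly(A) spikes brighter than the median probe set (13 of 24 sets), on all 24 sets or on the hybridization controls was added after the data were seen.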

Results

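Transcript levels were measured on 6 Affymetrix ATH1 arrays of rosettes of the Arabidopsis catalase mutant cat2-2 in the Col-0 background. The mutant lacks normal function of the main leaf catalase, which removes hydrogen peroxide made in photorespiration. In the untreated group, 3 biological replicates were taken at 0 h from plants 21 days old. In the treated group, 3 biological replicates were taken 24 h later, at 22 days, after the plates had been resealed to restrict gas exchange and moved to continuous light, which the submitters call photorespiratory conditions. Values are RMA log2 levels of 22746 probe sets without the control sets, with array medians between 6.22 and 6.27. The comparison asks how transcript levels of this mutant differ after the treatment. All fold changes below are treated against untreated with n = 3 arrays per group, errors after ± are standard errors (SE) of the log2 fold change, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over all probe sets. The small number of arrays limits the precision.

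After 24 h of treatment, the mutant rosettes held more transcript of the glutathione S-transferase GSTU25 (10.01-fold), of the glycosyltransferase UGT73B4 (6.81-fold), of the defensin PDF1.2 (24.8-fold) and of the leucine breakdown enzyme IVD (9.56-fold). They held less of the cold-regulated chloroplast protein COR15A (11.9-fold lower), of the glucosinolate enzyme BCAT4 (10.6-fold lower), of the expansin gene EXPA8 (9.08-fold lower) and of the chlorophyll synthesis enzyme PORB (6.27-fold lower). Of 22746 probe sets, 9479 (41.7%) changed, 4420 higher and 5059 lower, and 1869 of these changed at least 2-fold, 984 higher and 885 lower. Changes of at least 4-fold comprised 253 higher and 127 lower probe sets. Counted as genes, with 1 probe set each, 5034 of 13356 changed, 2276 higher and 2758 lower.

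The groups did not overlap, with all 3 treated arrays on one side of all 3 untreated arrays, for 11544 probe sets (50.8%), where chance gives 10%. The first principal component, which separated the groups, held 89.4% of the variance, and Pearson's r across probe sets, which are not independent replicates, was 0.996 to 0.997 within groups and 0.955 to 0.966 between them. The balance of higher and lower calls depended on how arrays were scaled. With arrays anchored on the bacterial poly(A) spikes, a setting chosen after seeing the data that used the 13 of 24 spike sets brighter than the median probe set, 65.0% of 8688 changed probe sets were higher, and with arrays anchored on the hybridization controls, also chosen afterwards, 71.2% of 6644 were higher, against 46.6% in the values as deposited. Among changes of at least 2-fold, the shares higher were 63.8% and 69.2% in these settings, against 52.7% as deposited. With arrays anchored on all 24 spike sets, added later still, the shares were 54.7% of 8933 and 57.4% of 1873, so their size rests on which spike sets were used. The first 2 settings raised every treated minus untreated log2 difference by 0.14 and 0.21 and that with all 24 sets by 0.06, so the changes below are relative to the bulk of transcripts as RMA scaled it. The 13 brighter spike sets differed by -0.14 between groups (exact permutation test, two-sided p = 0.20), all 24 by -0.06 (exact p = 0.30) and the hybridization controls by -0.21 (exact p = 0.30), where the smallest p that 3 against 3 arrays allow is 0.10.

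**Figure D1:**
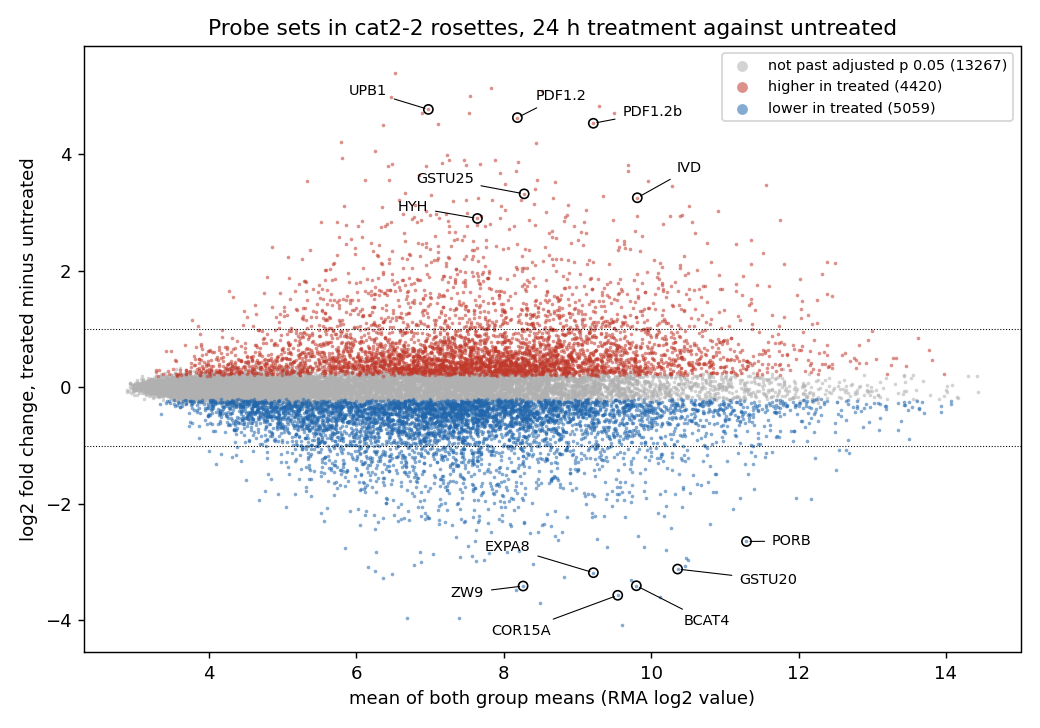
Each point is 1 of 22746 probe sets, with the mean of both group means (RMA log2 value) on the x axis and the log2 fold change, treated minus untreated, on the y axis. Red points (4420) were higher and blue points (5059) lower at an adjusted p under 0.05, dotted lines mark 2-fold, and rings mark named genes from UPB1 (log2 4.77) down to COR15A (log2 -3.57).

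Among genes with a symbol, the largest measured increase was in UPB1, a bHLH transcription factor known for its part in the balance of reactive oxygen species in roots, at 27.3-fold (log2 4.77 ± 0.11; adjusted p = 7.88e-10). Its untreated mean of 4.59 lay at the 27.8th percentile of probe sets. Whether that is above background was not tested, so the size of the fold and its rank are uncertain. The defensin genes PDF1.2 and PDF1.2b followed with 24.8-fold (log2 4.63 ± 0.44; adjusted p = 5.82e-06) and 23.2-fold, and both varied between the untreated arrays, with PDF1.2 at 5.57, 4.83 and 7.21. Without untreated replicate 3 the PDF1.2 difference was 39.5-fold, and without untreated replicate 2 the PDF1.2b difference was 14.04-fold. The probe set of PDF1.2b shares probes with near-identical genes, so its level is uncertain. The remaining 7 of the 10 strongest increases were GSTU25 (log2 3.32 ± 0.21; adjusted p = 2.55e-07), IVD (log2 3.26 ± 0.15), the organ growth gene ARL at 8.28-fold, the light-signalling bZIP factor HYH at 7.47-fold, UGT73B4, UGT73C1 at 6.33-fold and EXO, a brassinosteroid-responsive gene of leaf growth, at 6.06-fold.

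The strongest decrease among genes with a symbol was in COR15A (log2 -3.57 ± 0.17; adjusted p = 4.14e-08), followed by ZW9 at 10.65-fold lower and BCAT4 (log2 -3.41 ± 0.10; adjusted p = 1.85e-09). The 10 strongest decreases also held the expansin genes EXPB1 (9.68-fold lower, with a treated mean at the 30.6th percentile), EXPA8 (log2 -3.18 ± 0.15) and EXPB3 (7.97-fold lower), the endoglucanase-type gene GH9C2 (7.18-fold lower) and the xyloglucan-modifying XTH32 (5.15-fold lower). Of 10 EXPA genes 3 fell and 1 rose (camera, adjusted p = 0.135; the median of -0.09 turned to 0.05 when anchored on the poly(A) spikes), and of 9 XTH genes 5 rose and 1 fell (adjusted p = 0.174). GSTU20 fell 8.70-fold and PORB, at log2 -2.65 ± 0.09, completed the 10. Most measured genes carry only a locus tag, and among these, which stand outside the rule for named genes and were picked by the same order of size, AT4G10270 rose 26.2-fold (untreated mean at the 26.8th percentile) and AT5G05600 15.0-fold, while AT4G30650 fell 13.05-fold and AT5G03350 12.1-fold.

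In the gene lists below, a measured member is one whose locus carried an accepted symbol. List tests below are camera unless stated. With an estimated correlation, camera takes its degrees of freedom from the 6 arrays, not from the number of genes, which lowers its power. With fry, which does not compare a list with other genes, every tested list passed except Calvin-Benson (adjusted p = 0.166) and guard cell (0.182). Lists of antioxidant, heat shock, photosystem and flavonoid genes passed fry (adjusted p = 0.00118, 0.00233, 0.00805 and 0.0319) but not camera at its main setting. With 41.7% of probe sets changed, passing fry does not set a list apart. Of 9 measured glutathione S-transferases and UDP-glycosyltransferases, 6 rose and 3 fell. The risers were GSTU25, UGT73B4, UGT73C1, UGT73B5 (5.16-fold), GSTU22 (2.48-fold) and GSTU28 (1.70-fold), and the fallers were GSTU20, GSTU27 (1.68-fold lower) and GSTU26 (1.65-fold lower). The list test passed (camera, adjusted p = 0.0354). It did not pass with an estimated correlation (adjusted p = 0.202), after the arrays were shifted to equal medians (0.0656) or when anchored on all 24 spike sets (0.0590). With cameraPR on z scores it did not pass either, without moderation (adjusted p = 0.0994) or with trend and robust moderation (adjusted p = 0.133). In the wider GSTU family, of 11 genes 5 rose and 5 fell (camera, adjusted p = 0.846).

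Of 5 measured antioxidant enzymes, 3 rose and 1 fell. The stromal ascorbate peroxidase gene SAPX rose 2.18-fold (log2 1.13 ± 0.09), the monodehydroascorbate reductase gene ATMDAR2 2.04-fold and the glutathione reductase gene GR1 1.95-fold. The thylakoid ascorbate peroxidase gene TAPX fell 1.69-fold and the plastid glutathione reductase gene GR stood at log2 0.04 (adjusted p = 0.739). The list as a whole did not pass camera (adjusted p = 0.0901), though it passed fry (adjusted p = 0.00118). Both measured markers of oxidative and mitochondrial stress rose, the zinc-finger gene STZ 6.04-fold (log2 2.60 ± 0.17) and the mitochondrial dehydrogenase gene NDB2 1.26-fold. Of 3 heat shock genes, AT5G48570, a heat-induced FKBP-type gene with the synonym ROF2, rose 3.89-fold, and HSA32 (log2 0.13) and ATHSP22.0 (log2 0.03) did not pass (camera for the list, adjusted p = 0.112, 0.0334 when anchored on the hybridization controls, and 0.00479 with 7 members taken by locus alone). With an estimated correlation, camera gave adjusted p = 0.313 for the 3 genes and 0.191 for the 7.

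The hydroxypyruvate reductase gene HPR, the only member of the photorespiratory list with an accepted symbol, rose 1.17-fold (log2 0.23 ± 0.08; adjusted p = 0.0326), a call that was lost without untreated replicate 2 or 3 or treated replicate 1 or 2 (log2 0.20, 0.24, 0.22 and 0.21). With members taken by locus alone, 6 photorespiratory genes were measured, of which 3 rose and 3 fell. In sulfate assimilation and glutathione synthesis, the sulfite reductase gene SIR rose 1.55-fold and the ATP sulfurylase gene APS3 fell 1.39-fold. The latter call was lost with the arrays anchored on the poly(A) spikes (log2 -0.33) or the hybridization controls (log2 -0.26) and without moderation (adjusted p = 0.129). In iron homeostasis, the iron-deficiency factor BHLH101 fell 1.76-fold (without moderation, adjusted p = 0.0662) and PYE stood at log2 -0.09 (adjusted p = 0.478).

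All 4 measured genes of starch metabolism fell: DPE1, the plastid disproportionating enzyme, 2.71-fold (log2 -1.44 ± 0.09), APL3, a large subunit of ADP-glucose pyrophosphorylase, 2.59-fold, SBE2.2 1.33-fold and PWD 1.24-fold. The list passed (camera, adjusted p = 0.00373), with adjusted p = 0.202 with an estimated correlation. Leaving out the dimmest 40% of probe sets, APL3 among them, gave adjusted p = 0.0755, and with the arrays anchored on the poly(A) spikes or the hybridization controls 2 of the 4 fell, and on all 24 spike sets 3.

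Of 3 measured genes of senescence, chlorophyll breakdown and carbon starvation, 2 rose: EXO, and WRKY6, a transcription factor of leaf senescence, at 5.48-fold (log2 2.45 ± 0.11). WRKY53 stood at log2 0.28 (adjusted p = 0.0661). The list passed (camera, adjusted p = 0.00373; with an estimated correlation, adjusted p = 0.202), and EXO is known for growth and sugar-dependent expression, not for senescence.

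Of 8 measured photosystem and light-harvesting genes, 5 fell and 1 rose. LHCB4.2 fell 1.84-fold (log2 -0.88 ± 0.08), and the smaller decreases were in PSBY, PSAE-1, PSAN and LHCB4.1 (log2 -0.38 to -0.24). LHCB4.3, another gene of the CP29 antenna protein, rose 2.84-fold. With the arrays anchored on the poly(A) spikes 1 of the 8 fell, with all 24 spike sets 3, and the list test did not pass (camera, adjusted p = 0.108). The list did pass cameraPR on z scores, without moderation (adjusted p = 0.0222) and with trend and robust moderation (adjusted p = 0.0461). None of 3 Calvin-Benson genes changed: RCA, the activase of Rubisco, stood at log2 0.19 ± 0.07 (adjusted p = 0.0625), PRK at 0.06 and SBPASE at -0.08 (camera, adjusted p = 0.677). RCA passed in some settings, with log2 0.33 (adjusted p = 0.0333) when anchored on the poly(A) spikes.

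**Figure D2:**
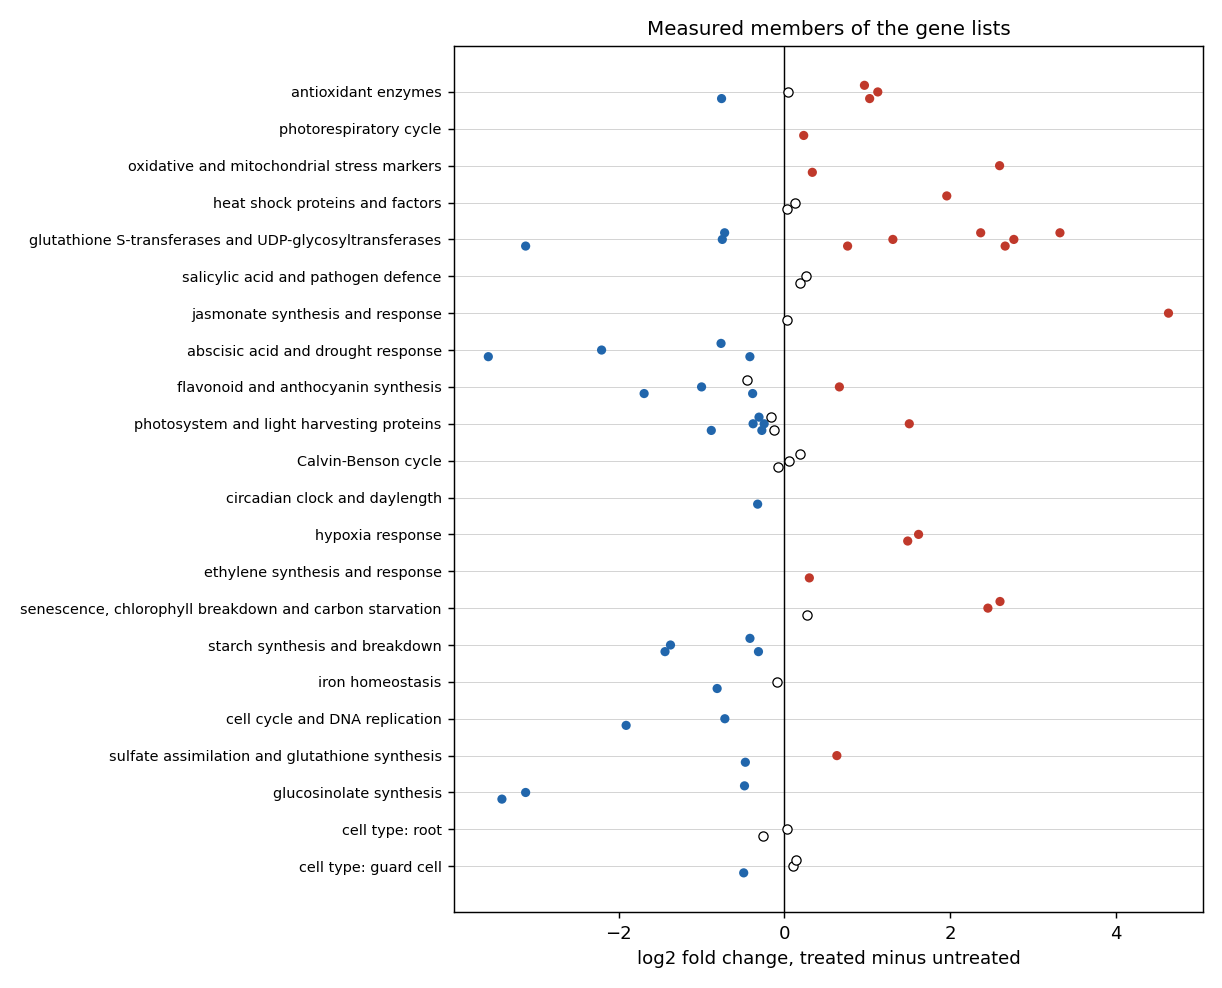
Each point is a measured member of a gene list fixed before the data were examined, with its log2 fold change, treated minus untreated, on the x axis and the list on the y axis, offset vertically for legibility. Filled red and blue points were higher and lower at an adjusted p under 0.05 and open points did not pass; all 4 abscisic acid and drought genes and all 4 starch genes lie to the left of 0 in the values as deposited.

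All 4 measured genes of abscisic acid and drought response fell: COR15A, its close homologue COR15B (4.61-fold lower, log2 -2.21 ± 0.15), and the dehydrins LTI30 (1.70-fold lower) and COR47 (1.33-fold lower). These genes are known from cold as well as drought. The list passed (camera, adjusted p = 0.00373), with adjusted p = 0.202 with an estimated correlation, and 3 of the 4 fell with the arrays anchored on the poly(A) spikes or the hybridization controls. All 3 measured glucosinolate genes fell: BCAT4, which starts chain elongation of methionine, GSTU20, which also stands in the glutathione S-transferase list, and UGT74B1 (1.396-fold lower). That list passed (camera, adjusted p = 0.00353; with an estimated correlation, adjusted p = 0.202), and 2 of the 3 fell with the arrays anchored on the hybridization controls.

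Of 5 measured flavonoid and anthocyanin genes, 3 fell and 1 rose. DFR, the dihydroflavonol reductase, fell 3.23-fold (log2 -1.69 ± 0.15), the flavonol rhamnosyltransferase gene UGT78D1 2.00-fold and AT5MAT 1.304-fold, while UGT78D2, a flavonoid glucosyltransferase gene, rose 1.58-fold and UF3GT stood at log2 -0.45 (adjusted p = 0.0615). The list did not pass (camera, adjusted p = 0.138), but did with the arrays anchored on the poly(A) spikes (adjusted p = 0.0400) or the hybridization controls (adjusted p = 0.0334), though not on all 24 spike sets.

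Both hypoxia genes with an accepted symbol rose, AT3G10040, a transcription factor gene with the synonym HRA1, 3.07-fold (log2 1.62 ± 0.09) and the pyruvate decarboxylase gene PDC2 2.80-fold (log2 1.49 ± 0.12). The hypoxia locus AT4G17260, without an accepted symbol, fell (log2 -0.35). Both measured cell cycle genes fell, the replication helicase gene PRL 3.76-fold (log2 -1.91 ± 0.09) and the mitotic kinase gene AUR1 1.65-fold. Of 2 jasmonate genes PDF1.2 rose and JMT stood at log2 0.03. Neither of 2 salicylic acid and defence genes passed, SAG101 at log2 0.26 (adjusted p = 0.0734) and GRX480 at 0.18. SAG101 did pass without untreated replicate 3 (log2 0.35; adjusted p = 0.0246) and with the arrays anchored on the poly(A) spikes (log2 0.40; adjusted p = 0.00998).

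The ethylene factor gene EIN3 rose 1.23-fold (log2 0.30 ± 0.10; adjusted p = 0.0297) and the clock gene GI fell 1.25-fold (log2 -0.32 ± 0.11; adjusted p = 0.0350), and both calls were lost when single arrays were left out. That of EIN3 was lost without untreated replicate 2 or 3 or treated replicate 2 or 3 (log2 0.23, 0.28, 0.24 and 0.32), with repeated quantile normalization (adjusted p = 0.0710) and without moderation (adjusted p = 0.130). That of GI was lost without untreated replicate 3 (log2 -0.20) or treated replicate 1, 2 or 3 (log2 -0.36, -0.33 and -0.28), and with the arrays anchored on the poly(A) spikes (log2 -0.18), all 24 spike sets (log2 -0.26) or the hybridization controls (log2 -0.11) and without moderation (adjusted p = 0.168).

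Of the markers of other cell types, 2 root hair and 3 guard cell genes were measured, and none of the vascular, epidermis or flower lists. The root hair expansins EXPA7 (log2 0.03) and EXPA18 (log2 -0.26; adjusted p = 0.144) did not pass, although EXPA18 did without untreated replicate 1 (log2 -0.44; adjusted p = 0.00179). Of 3 genes of the guard cell lineage, SPCH, which starts it, fell 1.41-fold (log2 -0.49 ± 0.09; log2 -0.28 and adjusted p = 0.230 when anchored on the hybridization controls), and MUTE (log2 0.11) and FMA (log2 0.14) did not pass (camera, downward, adjusted p = 0.849; median log2 0.11 and mean -0.08).

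In the check of RNA quality, the level at the 3' end minus that at the 5' end of control transcripts was smaller in treated arrays for 3 of 6 control pairs and larger for the other 3. The differences, treated minus untreated, were -0.31 for GAPDH, -0.30 for actin and -0.07 for ubiquitin in the older design of these controls, and 0.10, 0.13 and 0.13 for the same transcripts in the newer design, with exact two-sided permutation p = 0.10 (p = 0.30 for -0.07), where the smallest p possible is 0.10.

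**Figure D3:**
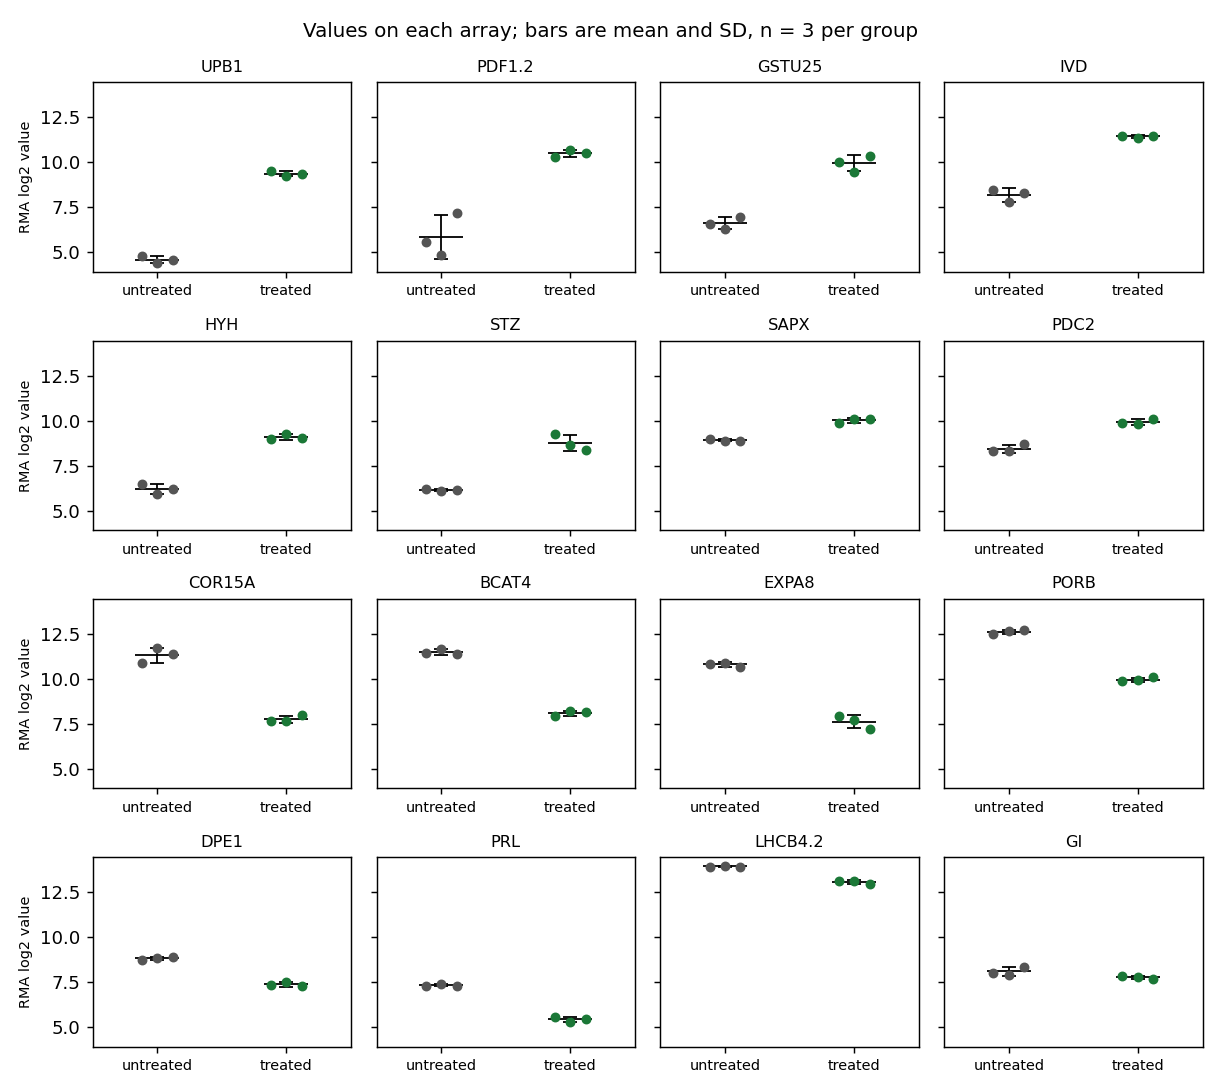
Points are RMA log2 values of 16 named genes on each of 3 untreated (grey) and 3 treated (green) arrays, with horizontal bars for the group mean and whiskers for the SD. The untreated arrays of PDF1.2 range from 4.83 to 7.21, while those of UPB1 lie between 4.40 and 4.78 against 9.21 to 9.51 in treated arrays.

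Adjusted over the list alone, the counts of members that rose or fell in the lists fixed before the data were examined, with accepted symbols, equalled those given above, except that WRKY53 raised the senescence and starvation count to 3 and UF3GT raised the flavonoid count of decreases to 4. Restricted gas exchange, continuous light and 1 more day of age differed together between the groups, and neither an untreated group at 24 h nor a wild type was analysed here, so the share of each in a change cannot be told apart.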

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

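Control probe sets outside the tested set carried a difference between the groups. Of 64 such sets, 11 were higher and 13 lower in treated arrays after adjustment over the control sets with limma, with all values on the log2 scale and 3 arrays per group.

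The GAPDH control sets of the older design were higher by 0.45 at the 3' end (adjusted p = 8.32e-04), by 0.77 at the 5' end (adjusted p = 1.03e-04) and by 0.52 in the middle (adjusted p = 2.58e-04), and those of the newer design by 0.64 at the 3' end and 0.55 at the 5' end. GAPDH is glyceraldehyde-3-phosphate dehydrogenase. The ubiquitin sets of the older design were higher by 0.41 at the 3' end, 0.48 at the 5' end and 0.43 in the middle (adjusted p = 8.32e-04, 7.36e-04 and 0.00552), and those of the newer design by 0.42 and 0.29 at the 3' and 5' ends (adjusted p = 7.36e-04 and 0.0147). The actin sets moved the other way, by -0.68, -0.75 and -0.38 for the 3' end, middle and 5' end in the older design and by -0.65, -0.82 and -0.79 in the newer one. The set for the 5' end of the bacterial spike phe was higher by 0.32 (adjusted p = 0.0193), while the sets for its 3' end and middle in the same design stood at -0.04 and -0.04 and did not pass. All 7 other bacterial or hybridization control sets that passed were lower: 4 of dap (-0.25, -0.22, -0.20 and -0.32), 2 of bioD (-0.29 and -0.24) and 1 of bioC (-0.24), with adjusted p from 0.00669 to 0.0393.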

How the results depend on the processing

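The scaling on poly(A) spikes and on hybridization controls and the leaving out of single arrays in the check of RNA quality were chosen after seeing the data; the other settings were fixed before. Counts of changed probe sets (9479) and of those changed at least 2-fold (1869) stayed within 1.5 times in every setting, from 6644 with arrays anchored on hybridization controls to 9572 with repeated quantile normalization, and from 1764 with the dimmest 40% of probe sets left out to 2699 with treat. Leaving out each array in turn gave 8408 to 8913 and 1772 to 1969. The number of gene lists past the threshold with camera was 5, also without any single array. It was 3 when the dimmest 40% of probe sets were left out, where fewer members remained, and 0 with an estimated correlation. Correlated members are not the whole cause of that loss. For the glutathione S-transferase list the estimated correlation was -0.04, below the preset 0.01, yet p rose from 0.0161 to 0.0667 (camera, unadjusted). Camera with an estimated correlation also takes its degrees of freedom from the 6 arrays, not from the number of genes, which raises p. How much each part contributed in the other lists was not tested. The number of lists was 4 with equal medians and with all 24 poly(A) spike sets, 6 and 7 with arrays anchored on the 13 brighter spike sets and the hybridization controls, and 7 with members taken by locus. It was 5 with trend and robust moderation and without moderation too, both tested with cameraPR. Of these, 4 were the same lists, with the photosystem list in place of the glutathione S-transferase list. The 3 of 6 control pairs with a smaller 3' minus 5' difference stayed 3 without any single array. Over all settings, the values of single genes kept their side of the threshold 1131 times, passed newly 11 times and no longer passed 25 times; for lists these numbers were 426, 5 and 33, and no direction of a gene or of a list test reversed, though the medians of the EXPA, GH and SCPL families changed sign when arrays were anchored on spikes (0.05, 0.03 and 0.01 with the 13 brighter sets, though not with all 24). The cause of the single-gene losses was not tested. Genes left with no probe set and lists left with under 3 members by a filter have no value there, and the catalase genes have none in any setting.

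With the replicate number as a block, 9190 probe sets changed, 1869 at least 2-fold, and 5 lists passed; of the named genes HPR (adjusted p = 0.0527) and EIN3 (adjusted p = 0.0503) lost their calls. Deviations of same-numbered arrays correlated at 0.07, -0.06 and 7.66e-04, and untreated 2 correlated best with treated 3 (0.10). No deviation common to same-numbered arrays was thus seen, which cannot show whether they shared a plate or batch. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 9479 changed probe sets and the highest other 0; for changes of at least 2-fold it was 1 of 10, with 1869 against 0, and for gene lists 1 of 10, with 5 against 1. With 10 splits the share cannot fall under 0.1, which is too few for a share under 0.05. All other splits mix treated and untreated arrays, so the group difference enters their spread. Their low counts are therefore no measure of chance. Values of probe sets near background may limit small changes there. Leaving out the dimmest 40% gave 8462 changed probe sets among the 60% kept, and 8170 of them were also called without the filter. The filter changed both the tested set and the adjustment, so this count cannot show that limit.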

Other observations

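Of the tests here, those of array scaling and of RNA degradation were chosen after related results had been seen, and the starvation markers were chosen after the amino acid result but before their own values; the lists were set after the gene table was seen and before any value. Of 51 such lists, 15 passed camera with its preset correlation and none passed with an estimated correlation, where the lowest adjusted p was 0.346.

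All 5 measured beta-tubulin genes fell, with TUB5 3.20-fold lower and TUB7 2.72-fold lower (camera, adjusted p = 1.47e-04; 0.346 with an estimated correlation; 4 of 5 fell when anchored on the hybridization controls). Of 6 CLE peptide genes 5 fell, led by CLE41 (2.71-fold lower) and CLE44 (2.42-fold lower), which are known to maintain vascular stem cells (adjusted p = 0.00394; 0.346; 4 of 6 fell when anchored on the poly(A) spikes or the hybridization controls). Of 15 IQD genes, which encode calmodulin-binding proteins, 8 fell and 2 rose, with iqd21 3.92-fold and IQD31 3.25-fold lower (adjusted p = 0.00791; 0.346). Of 19 genes with the prefix GH, a mix of endoglucanase-type GH9 and auxin-conjugating GH3 genes, 7 fell, among them GH9B8 (4.35-fold lower) and GH3.9 (2.73-fold lower; adjusted p = 0.0221; 0.346; without untreated replicate 1, adjusted p = 0.0518, and without moderation, 0.0566), and the median of -0.11 turned to 0.03 when anchored on the poly(A) spikes. Of 29 serine carboxypeptidase-like SCPL genes 11 fell and 2 rose (adjusted p = 0.0272; 0.494; without untreated replicate 3, adjusted p = 0.0699), and their median of -0.13 turned to 0.01 in that scaling, where 9 fell and 4 rose; 6 fell and 3 rose when anchored on the hybridization controls.

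Of 7 calmodulin-like CML genes 6 rose, CML38 3.17-fold (camera, adjusted p = 0.00347; 0.346 with an estimated correlation). Of 6 WRKY genes 3 rose, WRKY22 2.69-fold besides WRKY6 (adjusted p = 0.0129; 0.494). Of 47 UGT genes 19 rose and 7 fell, with UGT76E12 5.96-fold and UGT87A2 5.07-fold higher (adjusted p = 0.0120; 0.494). Of 9 further heat shock genes taken by locus 7 rose and 2 fell, AT2G29500 by 4.84-fold and Hop3 by 3.15-fold (adjusted p = 0.00567; 0.494). The prefix PDF joins defensins with unrelated proteins, and 5 of its 7 genes rose (adjusted p = 0.00627; 0.346). The remaining 34 families did not pass, though some members moved far: among sugar transporters SWEET2 was 4.61-fold higher, and SWEET13 and SWEET4 were 4.34-fold and 3.22-fold lower; among autophagy genes ATG8H was 3.61-fold and ATG8B 2.84-fold higher; and XTH19 was 5.49-fold higher. When the dimmest 40% of probe sets were left out, the lists of IQD, UGT and WRKY genes (adjusted p = 0.0819, 0.0819 and 0.164), of further heat shock genes (0.217) and of plastid ndh genes (0.0819) did not pass.

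With list members taken by locus alone, without the symbol check, 6 photorespiratory genes were measured, of which 3 rose and 3 fell. AT1G80380 (log2 0.60) and LrgB (log2 0.38) rose beside HPR, and AT1G11860 (log2 -0.53), AT1G79870 (log2 -0.30) and AT1G32470 (log2 -0.24) fell. In the same setting the mitochondrial stress locus AT2G21640 was 5.69-fold higher and 3 of 7 heat shock loci rose, AT5G51440 7.19-fold and AT1G53540 6.85-fold besides AT5G48570, while AT5G37670 (log2 -0.02), AT1G52560 (log2 0.08), HSA32 and ATHSP22.0 did not pass. Of 3 hypoxia loci 2 rose and AT4G17260 fell (log2 -0.35). By locus 7 lists passed in place of 5, with those of heat shock (adjusted p = 0.00479) and of oxidative and mitochondrial stress (0.00297) added, and none did with an estimated correlation, where the lowest adjusted p was 0.191.

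Signals of genes counted as plastid-encoded were lower: 35 of 61 fell and 2 rose, with a median log2 fold change of -0.42. Genes were assigned to the plastid or the mitochondrion by the lower-case stem of their symbol alone, with no check of the locus. Mitochondrial genes that share a stem may therefore be among the 61. When anchored on the 13 brighter poly(A) spike sets 25 fell, on all 24 29 and on the hybridization controls 19. How well the 3' labelling captures organelle transcripts was not tested, so signals of plastid and mitochondrial genes may not follow transcript amounts. By group, 12 of 20 psa and psb genes fell (camera, adjusted p = 0.00145; 0.494 with an estimated correlation), 13 of 19 rpo, rps and rpl genes fell and 1 rose (0.00147; 0.497), 5 of 10 ndh genes fell (0.0143; 0.497) and 5 of 12 pet and atp genes fell and 1 rose (0.102, not passed). Of 14 mitochondrion-encoded genes 3 rose and 2 fell (adjusted p = 0.977). The scaling of the arrays as the whole cause is argued against by a median of -0.28 when anchored on the poly(A) spikes, with array medians differing by -0.44 ± 0.15 (SE; -0.52 ± 0.13 with all 24 sets), and of -0.21 when anchored on the hybridization controls, with array medians differing by -0.37 ± 0.14 (SE), though scaling may make up part of the size. Probe set brightness as the whole cause is argued against by 10000 random lists matched on level, which had a median of -0.03 and a 2.5th percentile of -0.16. Those lists drew genes at random, without the correlation among these genes. The percentile is therefore too narrow to serve as a test of chance. RNA degradation stays open, since 3 of 6 control pairs had a smaller 3' minus 5' difference and 3 a larger one; no biological explanation beyond the treatment as a whole was tested.

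Transcripts of cytosolic ribosomal proteins were slightly lower: 51 of 111 fell and 1 rose, with a median of -0.23 (camera, adjusted p = 5.04e-06; 0.668 with an estimated correlation). Brightness as the whole cause is argued against by the random lists matched on level, which had a median of -2.55e-04 and a 2.5th percentile of -0.0943. Those lists drew genes at random, while the estimated correlation in this list was 0.52. The percentile is therefore too narrow to serve as a test of chance. Scaling stays open: anchored on the poly(A) spikes the median was -0.0866 and 19 fell, with array medians differing by -0.16 ± 0.15 (SE), on all 24 sets 35 fell and the array medians of the groups overlapped, and anchored on the hybridization controls 6 fell.

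Genes of branched-chain amino acid breakdown were higher: 7 of 9 rose and 1 fell, with IVD, MCCA (5.69-fold), ETFQO (2.56-fold) and MCCB (1.98-fold) leading and AT5G09300 1.51-fold lower, a call lost when anchored on the hybridization controls (camera, adjusted p = 6.38e-04; 0.494 with an estimated correlation). Anchoring on the poly(A) spikes raised every difference by 0.14, so it could only raise the median, from 0.87 to 1.01, and cannot decide on scaling. The scalings tried left the median between 0.81 (repeated quantile normalization) and 1.08 (hybridization controls). A hypothesis is that carbon limitation may raise these genes, since they are known to rise in plants short of sugar; of 36 other starvation marker loci 9 were measured, 8 rose and 1 fell, with a median log2 of 1.499 (camera p = 9.59e-06; p = 0.144 with an estimated correlation), led by AT4G27450 (4.35-fold) and ATL8 (3.75-fold). Oxidative stress, restricted gas exchange, continuous light and age were not separated from it, and the plants grew on sucrose, so this remains a hypothesis.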
